A study of Mus musculus with 8 samples.

How the data were processed

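Single-cell RNA was measured with the 10x Genomics 5' kit in 8 libraries of mouse Th17 cells, helper T cells that secrete interleukin 17. The cells were differentiated in culture, either in conditions the labels call pathogenic (Th17p) or in non-pathogenic conditions (Th17n), each in medium with 1 mM or 25 mM glucose. The 4 groups each hold 2 libraries, made from 2 mice that the labels call biological replicates, and the animal label gives each library its replicate number. Each mouse therefore gave 1 library per group, and the mouse number pairs libraries across groups. The cytokines used in either condition, the culture time and the sex of the mice are not given in the sources used here.

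The values are whole-number counts of unique molecular identifiers (UMIs) per gene and barcode, in a matrix in which the authors had aggregated all libraries. Per the submitters' processing notes, the deposited counts were made with Cell Ranger 3.1.0 on the mm10 mouse genome. Both a matrix of called cells and a matrix of all barcodes were used. Libraries in them carry only a barcode suffix from 1 to 8, which was matched to the number at the end of each library name in the labels. That match rests on the number alone. Whether depth was equalised between libraries on aggregation is not given in the sources used here. Gene symbols and identifiers were taken from the matrix, and gene positions from the GENCODE M21 annotation of mm10, matched by identifier for 375 of the 375 genes chosen by the rule for named genes. Of the 31053 genes, 71 symbols occur more than once and were kept apart by identifier. A 5' count does not separate near-identical paralogs, so members of families such as the ribosomal proteins and metallothioneins carry some uncertainty about which copy was counted.

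Of 19203 called barcodes, 439 with fewer than 500 detected genes and 2344 with over 10% mitochondrial UMIs were left out, categories that can overlap. Scrublet, run in each library through scanpy 1.11.5, marked 102 doublets, 0.613% of the 16628 cells tested, which were also left out. This left 16526 cells. Clustering on 2000 variable genes, 30 principal components and 15 neighbours at resolution 1 gave 15 clusters, and 0 of them had 3 leading markers of another cell type, so no cells were removed by type. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

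Cells are not replicates, so UMIs were summed over the cells of each library and the 8 sums were tested. The filterByExpr rule of edgeR kept 12574 genes. The sums were scaled with TMM factors, which ran from 0.858 to 1.12, and fitted in one quasi-likelihood model with a mean per group over all 8 libraries. The common biological coefficient of variation was 0.103. There were 5 contrasts: 1 mM against 25 mM glucose in Th17n, the same in Th17p, Th17p against Th17n at 25 mM, the same at 1 mM, and the difference of the glucose responses (Th17p minus Th17n). A gene was called at an adjusted p below 0.05 (Benjamini-Hochberg, within a contrast). Changes are log2 values ± a standard error derived from the quasi-likelihood F statistic, the absolute log2 change divided by the square root of F. Levels are CPM (counts scaled to the effective library size), as mean ± SD over the 2 libraries of a group. An exact permutation test of 2 libraries against 2 cannot reach the threshold, so calls rest on the spread pooled over genes and groups.

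Gene lists fixed beforehand were tested with limma's camera at its preset correlation of 0.01 between genes, with adjustment over the 34 lists of a contrast, and again with the correlation estimated from the data. The metabolic lists were glycolysis, hypoxia and HIF targets, glucose-induced MondoA and ChREBP targets, pentose phosphate pathway, hexosamine precursors, serine and one-carbon metabolism, oxidative phosphorylation, TCA cycle, glutamine and amino acid use, cholesterol synthesis, fatty acid synthesis and fatty acid oxidation. The stress and growth lists were the ATF4 stress response, the unfolded protein response of the endoplasmic reticulum (ER), NRF2 and redox, autophagy and lysosome, p53 targets, MYC targets, S phase, G2/M phase, cytosolic ribosomal proteins and mitochondrially encoded genes. The immune lists were the Th17 program, the pathogenic and the non-pathogenic Th17 signature, Th1 and cytotoxic, Th2, Treg, TGF-beta response, exhaustion, naive and central memory, activation and NF-kB, interferon response and immediate early genes. Markers of other cell types were fixed as well.

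The named genes were, for each contrast, the 8 largest rises and the 8 largest falls among called genes with a mean of at least 20 CPM and the same sign in each mouse. To these were added a panel of 12 Th17 genes, of which 11 passed the count filter, and up to 4 members per list with the smallest p. Some of the genes so chosen are not reported here. This rule, the groups, the tests, the lists and most alternatives were chosen before the data were examined.

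For shares of cells with a UMI of a gene, each cell was thinned to 5000 UMIs and shallower cells were left out. Free RNA was read from barcodes with over 100 and at most 1000 UMIs outside the called cells. Ratios resting on few UMIs are given with a 95% counting interval, which covers counting error only. Where a group had no UMI, no ratio was formed and only the lower limit of that interval was computed.

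The alternatives were DESeq2 size factors, no filter on low counts, the DESeq2 Wald test, the mouse as a block, each library left out in turn, all called barcodes, a minimum of 1000 genes per cell, doublets kept, an equal 1297 cells per library with sums thinned to 19786888 UMIs, and a fit of only the 4 libraries compared. Leaving out a library leaves a group with 1 library, which is then assumed to vary like the others. Alternatives chosen after the data had been seen were deep cells only (at least 8000 UMIs and at most 4% mitochondrial), the remaining shallow cells, and the leave-out fits of the gene lists. The pairing was checked by correlating the deviations of libraries of the same mouse from their group means, which gave r across genes of 0.238, 0.261, 0.09, 0.141, 0.197 and 0.228 for the 6 pairs of groups.

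The tests were tested on simulated data: counts were drawn for the 12574 genes from the real means and library sizes, with 200 genes changed and, for glucose in Th17n, 2 further lists of 20 genes moved. For glucose in Th17n, 28.6% of genes with a true log2 change of 0.5, 65% with 1 and 95.2% with 2 were recovered, and 13.1% of calls were false. For glucose in Th17p the values were 23.4%, 71.6% and 95.2%, with 9.3% false. For Th17p against Th17n they were 25.5%, 76.3% and 94.2% at 25 mM, with 7.4% false, and 15.9%, 64.4% and 89.1% at 1 mM, with 6.6% false. For the difference of the responses, 2.9%, 51.5% and 89.2% were recovered, with 6.9% false. In the simulated glucose contrast of Th17n, camera with its preset correlation called 2 of 2 moved lists and 0 of 100 unmoved ones, and with an estimated correlation it called 0 of 2. The simulated genes were independent, so the simulation does not show how often lists of correlated genes are called by chance. It changed far fewer genes than were called in every real contrast but the difference of the responses. Its recovered and false shares therefore need not carry over to those contrasts.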

Results

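The transcriptomes of single mouse Th17 cells were compared between low (1 mM) and high (25 mM) glucose in non-pathogenic (Th17n) and pathogenic (Th17p) culture conditions, with 2 mice per group and 8 libraries in all. The design asks how glucose supply affects each kind of Th17 cell, how the pair differ at each glucose level, and whether they respond alike. After filtering, 16526 cells remained, 1297 to 2531 per library. Libraries held 21854408 to 39554979 UMIs in cells, with a median of 16170.5 to 17910 UMIs per cell. Th17p libraries in 1 mM glucose were the smallest, with 1502 ± 289 cells (SD, n = 2), against 2111 ± 123 in Th17p at 25 mM, 2193 ± 479 in Th17n at 1 mM and 2458 ± 25.5 in Th17n at 25 mM.

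All 11 CD4 T cell markers lay above 10 CPM (median 161 CPM), and no marker of gamma-delta T cells, NK or innate lymphoid cells, plasma cells, neutrophils, mast cells, erythroid cells or platelets did. Genes of other types above 10 CPM were Cd8b1 (16.7 CPM), the B cell genes Ighm (18.7 CPM) and Ebf1 (13.6 CPM), the macrophage gene Ctss (30.9 CPM), and the antigen presentation genes H2-Ab1 (124 CPM) and Cd74 (48.8 CPM). H2-Ab1 lay above Cd4 (68.8 CPM) and ranged from 31.3 to 239 CPM between libraries, while the median of the 11 dendritic cell markers was 0.08 CPM. It was among the 10 leading genes of 2 of the 15 clusters, with 2235 and 2095 cells, nearly all from 1 mM libraries. The first principal component of the 8 sums, with 54.2% of the variance, separated Th17n from Th17p, and the second, with 28.9%, separated the glucose levels. Measures of RNA quality also moved with the groups. The median mitochondrial share of a cell's UMIs was 1.34 ± 0.078% in Th17n at 25 mM, 1.81 ± 0.031% in Th17n at 1 mM, 1.76 ± 0.098% in Th17p at 25 mM and 2.02 ± 0.077% in Th17p at 1 mM. Th17p at 25 mM had the largest share of shallow cells, 32.9 ± 4.26%, against 15.6 ± 0.425% in Th17p at 1 mM, 25.0 ± 4.75% in Th17n at 25 mM and 20.6 ± 0.852% in Th17n at 1 mM.

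**Figure D1:**
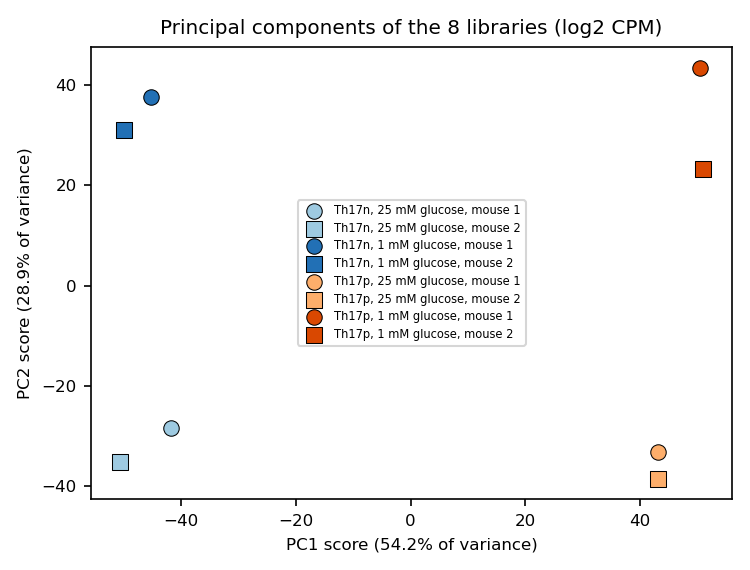
Principal components of the 8 library sums (log2 CPM; axes in component units, with 54.2% of the variance on the first and 28.9% on the second), each point a library. Th17n libraries lie between -50.6 and -41.8 on the first component and Th17p libraries between 43.1 and 50.9, and on the second component the 1 mM libraries lie between 23.2 and 43.5 and the 25 mM libraries between -38.5 and -28.5.

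In Th17n cells, 1 mM glucose lowered the transcripts of Il17a and Il17f and raised those of Mt1, Mt2, Nrn1 and Slc2a3. Il17a fell from 1726 ± 610 to 764 ± 292 CPM (log2 change -1.18 ± 0.28, edgeR adjusted p = 0.0124; SD, n = 2 per group), and Il17f from 1726 ± 416 to 718 ± 198 CPM (-1.27 ± 0.28, adjusted p = 0.0107). The largest rises included the metallothionein genes Mt1 (2.71 ± 0.34, adjusted p = 0.0012, from 420 ± 74.0 to 2745 ± 1250 CPM) and Mt2 (2.69 ± 0.35). Others were the neuritin gene Nrn1 (2.92 ± 0.20, adjusted p = 0.000266, from 12.1 ± 3.5 to 91.1 ± 3.29 CPM) and the glucose transporter gene Slc2a3 (2.74 ± 0.47). The cytochrome c oxidase subunit gene Cox6a2 (2.84 ± 0.35), Ndrg1 (2.56 ± 0.27) and the glycogen branching enzyme gene Gbe1 (2.46 ± 0.27) rose as well. The largest falls included Txnip, which encodes an inhibitor of glucose uptake (-2.30 ± 0.21, adjusted p = 0.00053, from 39.96 ± 9.09 to 8.07 ± 1.76 CPM). Further falls were those of Ly6a (-1.92 ± 0.19), the inhibitory receptor gene Tigit (-1.73 ± 0.27), Ly6e (-1.55 ± 0.15), and the mitotic genes Hmmr (-1.55 ± 0.20) and Plk1 (-1.47 ± 0.22). Of 12574 genes, 4289 were called, 2297 up and 1992 down, 913 of them by at least 2-fold. The count was 1472 without Th17n 1 mM mouse 1, 2786 without Th17n 25 mM mouse 1, 2839 without Th17n 1 mM mouse 2 and 2043 without Th17n 25 mM mouse 2. The call of Il17a was lost without Th17n 1 mM mouse 1 (adjusted p = 0.0727) and without Th17n 25 mM mouse 2 (0.0886), as was that of Il17f (0.0792 and 0.0734).

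Other panel genes of Th17n moved in either direction. Foxp3, the Treg lineage factor gene, fell (-1.36 ± 0.24, adjusted p = 0.0039, from 12.7 to 4.94 CPM), and Maf, which encodes a factor for Il10 transcription, rose (0.60 ± 0.11, adjusted p = 0.00488, from 58.6 to 88.7 CPM). Both calls were lost in shallow cells, where Foxp3 was at -0.87 (0.15) and Maf at 0.24 (0.271). Il10 rose from 2.17 to 4.02 CPM (0.89 ± 0.19, adjusted p = 0.00913), a call lost without Th17n 1 mM mouse 1 (0.08), without Th17n 25 mM mouse 2 (0.0598) and in shallow cells (0.16, adjusted p = 0.848). Csf2, which encodes GM-CSF, fell from 7.11 to 3.62 CPM (-0.95 ± 0.32, adjusted p = 0.0461), a call lost in deep cells (0.106) and with all barcodes (0.0507). It was also lost without Th17n 25 mM mouse 1 (0.211), Th17n 1 mM mouse 2 (0.179) and Th17n 25 mM mouse 2 (0.0669). Gzmb, the granzyme B gene, rose from 0.249 to 1.62 CPM (2.64 ± 0.58, adjusted p = 0.00988), a call lost without Th17n 25 mM mouse 2 (0.0641). Il23r (-0.87 ± 0.39, adjusted p = 0.119) passed only without the filter on low counts (0.0214), Tbx21 (0.09 ± 0.68, adjusted p = 0.929) did not pass, and Ifng, with too few UMIs, was not tested.

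Metabolic and stress lists moved in both directions in Th17n at 1 mM. Of 22 hypoxia and HIF targets, 21 rose and none fell (21 adjusted over the list alone). Their median log2 change was 1.38 (camera adjusted p = 1.57e-28, and adjusted p = 0.46 with an estimated correlation). They included the hormone gene Adm (4.49 ± 0.34), Ankrd37 (2.35 ± 0.11), the angiogenic factor gene Vegfa (1.78 ± 0.13) and the adenylate kinase gene Ak4 (1.37 ± 0.10). Of 28 ATF4 targets, 19 rose and 1 fell (22 and 1 adjusted over the list alone), among them Atf3 (1.57 ± 0.09), Trib3 (1.35 ± 0.12) and Atf4 itself (0.77 ± 0.09). This gave a median of 0.76 and a camera adjusted p = 1.39e-12 (adjusted p = 0.489 with an estimated correlation). Of 17 glycolysis genes, 11 rose (13 adjusted over the list alone), such as Slc2a1 (0.73 ± 0.12) and Slc2a3, though 6 rose without Th17n 1 mM mouse 1, 7 without Th17n 1 mM mouse 2 and 6 without Th17n 25 mM mouse 2. The list had a median of 0.49 (camera adjusted p = 0.00011; adjusted p = 0.566 with an estimated correlation). Cholesterol synthesis fell in 22 of 24 genes (23 adjusted over the list alone), with Mvd at -1.13 ± 0.09. As a set its median was -0.84, with adjusted p = 1.02e-21, and adjusted p = 0.489 with an estimated correlation. Fatty acid synthesis fell in 10 of 14 (10 adjusted over the list alone), with the elongase gene Elovl6 at -2.03 ± 0.21. Camera gave adjusted p = 2.03e-05 at a median of -0.44, and adjusted p = 0.489 with an estimated correlation. Those 10 were 5 without Th17n 1 mM mouse 1 and 6 without each of the other 3 libraries.

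TCA cycle genes fell in Th17n in 10 of 21 (1 up and 16 down adjusted over the list alone), including Fh1 (-0.90) and Suclg1 (-0.68), with 3 falling without Th17n 1 mM mouse 1 and 5 without Th17n 25 mM mouse 2. Across its members the median was -0.30 (camera adjusted p = 0.000289, and adjusted p = 0.567 with an estimated correlation). Oxidative phosphorylation fell in 13 of 42 (5 adjusted over the list alone), but in 0 without Th17n 1 mM mouse 1 or Th17n 25 mM mouse 2 and in 7 without Th17n 1 mM mouse 2, and the list was not called without Th17n 25 mM mouse 2 (0.0755). Its median was -0.16, at a camera adjusted p = 0.00603 and an adjusted p = 0.733 with an estimated correlation. The pentose phosphate pathway fell in 4 of 9 (5 adjusted over the list alone), led by Taldo1 (-0.71), with 1 falling without Th17n 1 mM mouse 1 and 2 without Th17n 25 mM mouse 2. Over the whole list the median change was -0.38 (adjusted p = 0.0102, and adjusted p = 0.489 with an estimated correlation). Fatty acid oxidation fell in 4 of 18 (3 adjusted over the list alone), with Acaa2 (-0.77) and Eci1 (-0.59), 2 falling without Th17n 1 mM mouse 1, and the list lost its call without Th17n 25 mM mouse 1 (0.0515). This gave a median of -0.21 and a camera adjusted p = 0.0175 (adjusted p = 0.53 with an estimated correlation). Lists without a call were hexosamine precursors (2 up, 4 down of 14; adjusted p = 0.564), serine and one-carbon metabolism (3 up, 5 down of 12, with Aldh1l2 up by 1.89 ± 0.26; adjusted p = 0.727), and glutamine and amino acid use (2 up, 5 down of 14; adjusted p = 0.462). Adjusted over the list alone these were 2 up and 4 down, 3 up and 6 down, and 4 up and 5 down. Of 4 tested targets induced by glucose through MondoA and ChREBP, only Txnip passed, over all genes and adjusted over the list alone, while Klf10 (0.14 ± 0.15), Arrdc4 (0.28 ± 0.40) and Arrdc3 (0.02) did not. Their median was 0.08 while the camera direction was down (adjusted p = 0.189), with a call without Th17n 1 mM mouse 1 (0.0446) and with the mouse as a block (0.0319).

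Proliferation genes fell in Th17n at 1 mM. Of 37 G2/M genes, 34 fell (35 adjusted over the list alone), such as the kinase gene Aurka (-1.41 ± 0.13) and Nusap1 (-1.12 ± 0.12), and 22 fell without Th17n 1 mM mouse 1. The list had a median of -0.94 (camera adjusted p = 1.43e-22; adjusted p = 0.489 with an estimated correlation). Of 30 S phase genes, 26 fell and 1 rose (27 and 1 adjusted over the list alone), such as Chaf1b (-1.01) and Clspn (-0.85), with 6 falling without Th17n 1 mM mouse 1 and 10 without Th17n 25 mM mouse 2. As a set its median was -0.61, with adjusted p = 1.15e-09, and adjusted p = 0.566 with an estimated correlation. MYC targets fell in 12 of 24 and rose in 1 (15 and 1 adjusted over the list alone), for example Nolc1 (-0.95), with 4 falling without Th17n 1 mM mouse 1 and 5 without Th17n 25 mM mouse 2. Camera gave adjusted p = 2.48e-05 at a median of -0.39, and adjusted p = 0.584 with an estimated correlation. Cytosolic ribosomal proteins rose in 57 of 78 and fell in 1 (67 and 1 adjusted over the list alone), but their single calls rested on each library: 0 rose without Th17n 1 mM mouse 1, 1 without Th17n 25 mM mouse 1 and 0 without Th17n 25 mM mouse 2, while the list kept its call. Across its members the median was 0.40 (camera adjusted p = 1.95e-08, and adjusted p = 0.678 with an estimated correlation). Mitochondrially encoded genes rose in 11 of 13 (11 adjusted over the list alone), among them mt-Nd5 (0.67 ± 0.09) and mt-Nd4 (0.65), with 7 rising without Th17n 1 mM mouse 1 and 6 without Th17n 25 mM mouse 2. Its median was 0.57, at a camera adjusted p = 1.39e-05 and an adjusted p = 0.489 with an estimated correlation. The median ribosomal share of a cell's UMIs was 24.9 ± 0.453% at 25 mM and 30.3 ± 2.56% at 1 mM, beside the mitochondrial shares given above. Barcodes with over 10% mitochondrial UMIs, left out beforehand, made up 5.25 ± 1.03% in Th17n at 25 mM and 10.9 ± 0.173% at 1 mM.

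Of the immune lists, 2 were called in Th17n, both with a rise. The TGF-beta response list rose in 10 of 16 and fell in 1 (10 and 1 adjusted over the list alone), with the receptor gene Tgfbr2 at 0.83, Ldlrad4, an inhibitor of the pathway, at 1.40 and Rgs16, a regulator of G protein signalling, at 1.64, while the tetraspanin gene Cd9 fell (-0.94). Over the whole list the median change was 0.61 (adjusted p = 0.000448, and adjusted p = 0.46 with an estimated correlation). The activation and NF-kB list rose in 9 of 20 and fell in 3 (11 and 4 adjusted over the list alone), led by Tnfaip3, an inhibitor of NF-kB (1.02 ± 0.12), and lost its call without Th17n 1 mM mouse 2 (0.174) and Th17n 25 mM mouse 2 (0.0831). This gave a median of 0.38 and a camera adjusted p = 0.0337 (adjusted p = 0.53 with an estimated correlation). The Th17 program showed 5 up and 4 down of 23 (6 and 5 adjusted over the list alone; median 0.00, adjusted p = 0.88), with Cxcr6 (1.68 ± 0.22), Rora (0.61) and Stat3 (0.52) up. In the pathogenic signature 4 of 16 rose and 3 fell (4 and 4 adjusted over the list alone; adjusted p = 0.886), with Lgals3 at 2.44 ± 0.41, Il7r at 1.01 ± 0.18 and Lrmp at -1.13 ± 0.15. In the non-pathogenic signature 2 of 7 rose (2 adjusted over the list alone; median -0.18, camera direction up, adjusted p = 0.88). Of 34 interferon response genes, 6 rose and 2 fell (3 up adjusted over the list alone; adjusted p = 0.616), with Isg20 at 2.87 ± 0.34 and Irf9 at 0.80. The Th1 list had 3 up, among them Runx3 (1.08 ± 0.10), and 3 down of 18 (the same counts adjusted over the list alone; adjusted p = 0.88).

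The remaining lists were also not called in Th17n. The Treg list had 4 up and 5 down of 17, with Ikzf2 at 1.60 and Izumo1r at -1.06 (median 0.18, camera direction down, adjusted p = 0.588), and the Th2 list 1 up and 2 down of 7 (adjusted p = 0.861). There were, in the naive list, 2 up and 2 down of 14, with Ly6c1 at -2.70 ± 0.38 (adjusted p = 0.462), and, among p53 targets, 4 up and 4 down of 16, with Bbc3 at 1.21 (adjusted p = 0.88). Immediate early genes had 5 up and 3 down of 18, with Jun at 1.14 ± 0.09 and the heat shock gene Hspa1a at -1.81 (adjusted p = 0.679). Autophagy genes had 3 up and 5 down of 22 (adjusted p = 0.741), and NRF2 targets 1 up and 5 down of 16, with Sod2 at -0.70 (adjusted p = 0.173). Counts adjusted over the list alone differed by more than 1 gene from these in none of the 7 lists. The exhaustion list had 1 up and 4 down of 13 (the same adjusted over the list alone; adjusted p = 0.164) and was called without Th17n 1 mM mouse 2 (0.0315) or Th17n 25 mM mouse 2 (0.0212). The ER unfolded protein response had 3 up of 21 (2 adjusted over the list alone), with Herpud1 at 0.70 (adjusted p = 0.427), and was called without Th17n 1 mM mouse 2 (0.0343).

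In Th17p cells, 1 mM glucose again lowered Il17a and Il17f and raised Mt1, Mt2 and Nrn1, while Csf2 and Gzmb rose. Il17a fell from 564 ± 25.2 to 116 ± 7.98 CPM (-2.28 ± 0.29, edgeR adjusted p = 0.00106; SD, n = 2 per group). Il17f fell from 733 ± 73.6 to 117 ± 47 CPM (-2.64 ± 0.30, adjusted p = 0.000725), and the IL-23 receptor gene Il23r fell from 10.9 ± 1.12 to 3.38 ± 1.09 CPM (-1.66 ± 0.25, adjusted p = 0.00193). Gzmb rose from 28.8 ± 9.82 to 116 ± 3.33 CPM (2.02 ± 0.25, adjusted p = 0.001). Csf2 rose from 36.2 ± 9.3 to 71.5 ± 19.5 CPM (0.98 ± 0.26, adjusted p = 0.0197), a call lost without Th17p 1 mM mouse 1 (0.102), without Th17p 25 mM mouse 2 (0.12) and in shallow cells (0.077, adjusted p = 0.845). The largest rises included Mt2 (2.87 ± 0.35), Mt1 (2.81 ± 0.34, from 406 ± 113 to 2850 ± 714 CPM) and Nrn1 (2.64 ± 0.19). They also included the annexin gene Anxa3 (2.56 ± 0.38), Gbe1 (2.50 ± 0.26), the TGF-beta superfamily receptor gene Acvrl1 (2.44 ± 0.38), Slc2a3 (2.42 ± 0.45) and the galectin gene Lgals3 (2.41 ± 0.41). The largest falls included Txnip (-3.93 ± 0.23, adjusted p = 0.000111, from 90.5 ± 18.0 to 5.92 ± 0.01 CPM) and the chemokine gene Ccl5 (-3.63 ± 0.59, from 69.2 ± 17.3 to 5.65 ± 0.985 CPM). Il24 (-2.64 ± 0.28), Timp1 (-1.97 ± 0.16), Hmmr (-1.85 ± 0.21) and Cdc20 (-1.84 ± 0.22) fell too. Il10 (-1.03 ± 0.55, adjusted p = 0.281), Foxp3 (-0.46 ± 0.81, 0.692), Maf (0.34 ± 0.29, 0.426) and Tbx21 (-0.96 ± 0.60, 0.25) did not pass, though Tbx21 did with the mouse as a block (0.00497), without the filter on low counts (1.14e-08) and in shallow cells (0.0308). In all 4025 genes were called, 2150 up and 1875 down, 973 by at least 2-fold. The count was 2517 without Th17p 1 mM mouse 1, 2441 without Th17p 25 mM mouse 1 and 2171 without Th17p 25 mM mouse 2.

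Of the metabolic and stress lists in Th17p, hypoxia and HIF targets rose in 20 of 22 (22 adjusted over the list alone), with Adm at 3.85 ± 0.31, Ankrd37 at 2.05 ± 0.11 and the prolyl hydroxylase gene Egln1 at 1.78 ± 0.13. The list had a median of 1.15 (camera adjusted p = 4.89e-25; adjusted p = 0.435 with an estimated correlation). Glycolysis rose in 13 of 17 (14 up and 1 down adjusted over the list alone), including Slc2a1 (0.85 ± 0.12), Hk1 (0.82) and Gapdh (0.76), with 8 rising without Th17p 25 mM mouse 2. As a set its median was 0.50, with adjusted p = 2.32e-06, and adjusted p = 0.499 with an estimated correlation. ATF4 targets rose in 17 of 28 and fell in 2 (18 and 2 adjusted over the list alone), with Trib3 at 1.15, Cebpb at 1.07 and Atf3 at 1.02 ± 0.09. Camera gave adjusted p = 3.1e-07 at a median of 0.59, and adjusted p = 0.499 with an estimated correlation. Cholesterol synthesis fell in 19 of 24 (21 adjusted over the list alone), with Dhcr7 at -1.66. Across its members the median was -0.68 (camera adjusted p = 9.14e-11, and adjusted p = 0.499 with an estimated correlation). Fatty acid synthesis fell in 8 of 14 and rose in 1 (8 and 1 adjusted over the list alone), with Acsl3 at -1.13 ± 0.10, but in 3 without Th17p 1 mM mouse 1 and 2 without Th17p 25 mM mouse 2, and the list was not called among deep cells (0.0622). Its median was -0.44, at a camera adjusted p = 0.000477 and an adjusted p = 0.499 with an estimated correlation. The MondoA and ChREBP targets fell in 3 of 4 tested (3 adjusted over the list alone): Txnip, the repressor gene Klf10 (-2.45 ± 0.21) and the arrestin domain gene Arrdc4 (-2.33 ± 0.43), while Arrdc3 did not pass (-0.27 ± 0.26). Over the whole list the median change was -2.39 (adjusted p = 7.6e-08, and adjusted p = 0.266 with an estimated correlation). Serine and one-carbon genes were not called as a list (4 up, 1 down of 12, the same adjusted over the list alone; median -0.01, camera direction up, adjusted p = 0.198), although Aldh1l2 (1.94), Mthfd2 (1.02 ± 0.09) and Mthfd1l (0.88) rose. Oxidative phosphorylation (7 up of 42, 1 adjusted over the list alone; median 0.12, adjusted p = 0.155) was called without Th17p 1 mM mouse 1 (0.0113) or Th17p 25 mM mouse 2 (0.0459).

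Proliferation genes fell in Th17p as well. Of 37 G2/M genes, 33 fell (35 adjusted over the list alone), with Aurka at -1.55 ± 0.13 and Nusap1 at -1.44. This gave a median of -1.10 and a camera adjusted p = 2.58e-27 (adjusted p = 0.499 with an estimated correlation). Of 30 S phase genes, 23 fell (1 up and 26 down adjusted over the list alone), with the cyclin E genes Ccne1 (-0.98) and Ccne2 (-1.06) and the licensing factor gene Cdc6 (-1.05). The list had a median of -0.81 (camera adjusted p = 3.43e-12; adjusted p = 0.501 with an estimated correlation). Cytosolic ribosomal proteins rose in 65 of 78 (68 adjusted over the list alone), such as Rps4x (0.84) and Rps3a1 (0.80 ± 0.10), with 43 rising without Th17p 1 mM mouse 1 and 39 without Th17p 25 mM mouse 2. As a set its median was 0.64, with adjusted p = 5.73e-20, and adjusted p = 0.501 with an estimated correlation. Mitochondrially encoded genes rose in 7 of 13 (7 adjusted over the list alone), led by mt-Co2 (0.59), with 3, 2, 3 and 2 rising without Th17p 1 mM mouse 1, 25 mM mouse 1, 1 mM mouse 2 and 25 mM mouse 2. Camera gave adjusted p = 0.0494 at a median of 0.31, and adjusted p = 0.698 with an estimated correlation. That list was not called without Th17p 25 mM mouse 1 (0.22), without Th17p 1 mM mouse 2 (0.117), with the mouse as a block (0.0587) or with DESeq2 size factors (0.0514). Ribosomal transcripts made up a median of 26.8 ± 0.504% at 25 mM and 33.8 ± 2.7% of a cell's UMIs at 1 mM, and the shares of shallow cells in these groups are given above.

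Among immune lists in Th17p, interferon response genes fell in 19 of 34 (1 up and 24 down adjusted over the list alone), including the interferon regulatory factor gene Irf7 (-2.42 ± 0.41), the GTPase gene Igtp (-1.49 ± 0.22), the peptide transporter gene Tap1 (-0.92) and Stat2 (-0.77), with 12 falling without Th17p 25 mM mouse 1. Across its members the median was -0.93 (camera adjusted p = 6.11e-08, and adjusted p = 0.266 with an estimated correlation). The Th17 program fell in 8 of 23 and rose in 4 (the same adjusted over the list alone; median -0.27, adjusted p = 0.0635), with Il1r1 at -2.13 ± 0.25 and Stat3 at 0.79, and was called without Th17p 25 mM mouse 1 (0.0416), without Th17p 1 mM mouse 2 (0.0106) and with the block (0.022). The Th1 list had 2 up and 3 down of 18 (2 and 5 adjusted over the list alone; adjusted p = 0.198), with Runx3 at 1.51 ± 0.10 and the chemokine receptor gene Cxcr3 at -1.37 ± 0.12. The pathogenic signature had 5 up and 5 down of 16 (the same adjusted over the list alone; adjusted p = 0.896), with Lgals3 up and Cxcl3 (-1.68) down. Of 20 activation and NF-kB genes, 8 rose and 3 fell (the same adjusted over the list alone; adjusted p = 0.32), with the adhesion gene Icam1 at -1.34 ± 0.09 and Relb at 0.62. Of 16 p53 targets, 2 rose and 6 fell (the same adjusted over the list alone; adjusted p = 0.0635), with Pmaip1 at -1.62, and the list was called without Th17p 25 mM mouse 2 (0.033) and in deep cells (0.0428). In deep cells the activation list was called too (0.0431). The remaining lists were not called with all libraries, with adjusted p from 0.0994 for exhaustion (3 down of 13, the same adjusted over the list alone) to 0.776 for NRF2 targets (4 up, 1 down of 16, median -0.02, camera direction up). Of these, exhaustion was called without Th17p 1 mM mouse 2 (0.0359) or 25 mM mouse 2 (0.0397), and fatty acid oxidation without Th17p 25 mM mouse 2 (0.0453) and in deep cells (0.0221). So were the non-pathogenic signature (0.0394) and MYC targets (0.0351) without Th17p 1 mM mouse 2, the Th2 list without Th17p 25 mM mouse 2 (0.045), and the ER unfolded protein response without Th17p 1 mM mouse 1 (8.11e-05).

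**Figure D2:**
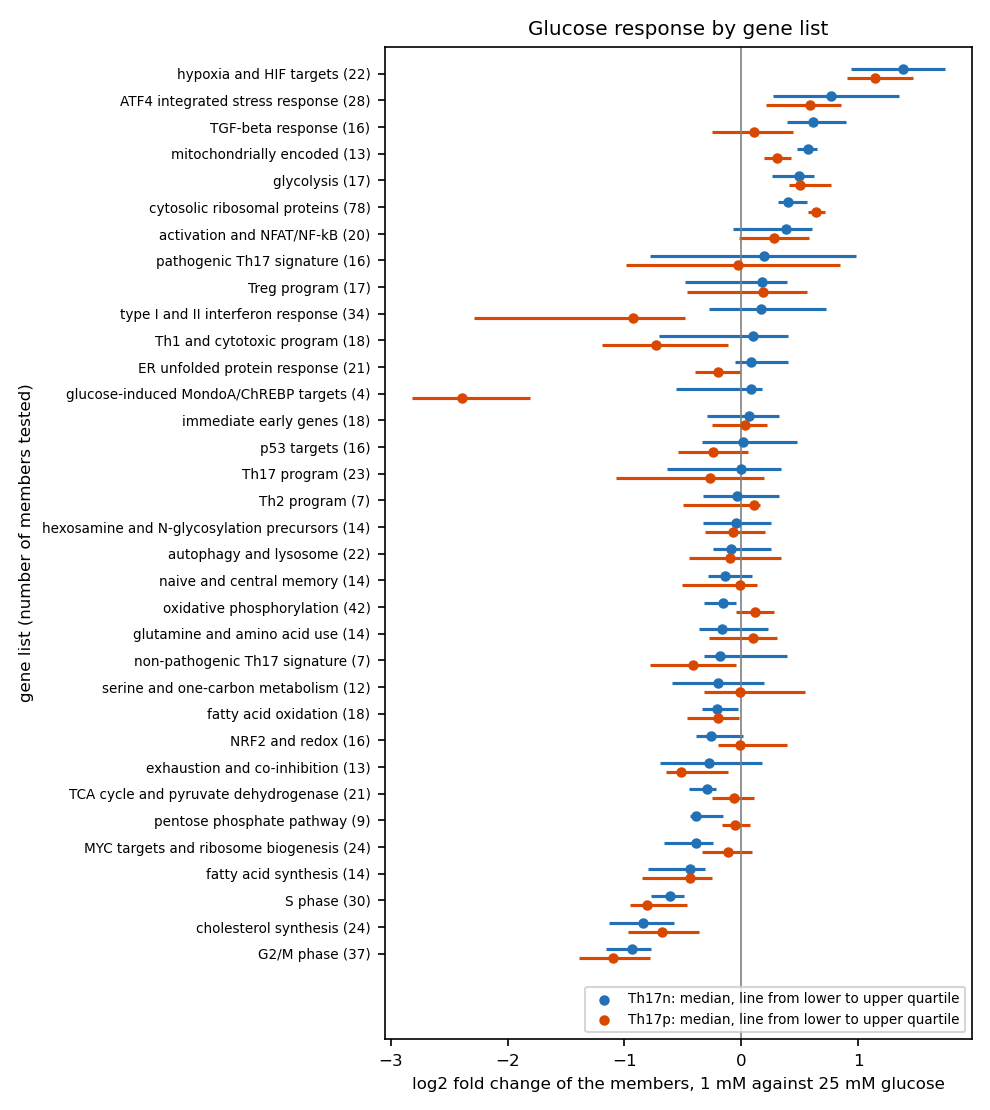
Log2 change of the members of each fixed list, 1 mM minus 25 mM glucose, with the median as a point and the quartiles as a line, for Th17n and Th17p. Hypoxia and HIF targets have medians of 1.38 and 1.15 and G2/M genes of -0.94 and -1.10, while the interferon response list has 0.16 in Th17n and -0.93 in Th17p.

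The glucose responses of Th17n and Th17p, which share no library, were compared across all 12574 genes. Among genes called in both, 1396 rose in both (393 for independent lists), 1098 fell in both (297) and 25 moved in opposite directions (683). The log2 changes correlated at r = 0.67 across genes, which are not independent replicates. The number moving the same way, 2494, was 1165 without Th17n 1 mM mouse 1, 1518 without Th17n 25 mM mouse 2 and 1548 without Th17p 25 mM mouse 2.

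**Figure D3:**
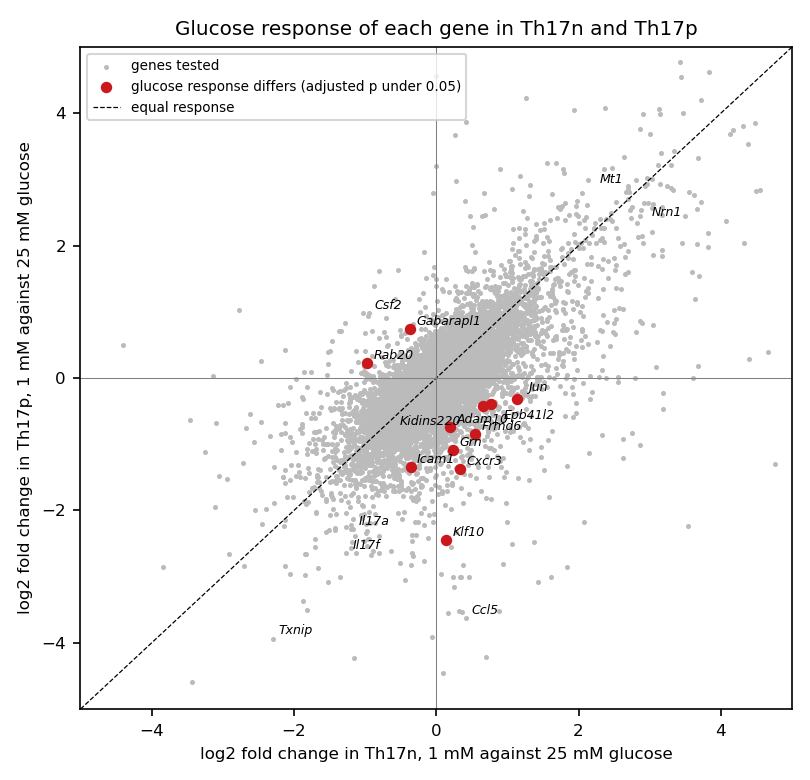
Log2 change of each gene with 1 mM against 25 mM glucose in Th17n (horizontal) and Th17p (vertical), with the 11 genes whose responses differed in red; of the genes tested, 24 lie outside the axis limits of 5. The correlation across genes is 0.67.

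The difference between the responses was tested gene by gene in the planned fit, which has no mouse term although the mouse pairs the libraries. In this fit 11 genes passed in edgeR, 2 with a higher and 9 with a lower response in Th17p. Jun, an AP-1 subunit gene, rose in Th17n from 52.97 to 116 CPM while it was 54.4 CPM at 25 mM and 43.5 CPM at 1 mM in Th17p (difference -1.46 ± 0.13, adjusted p = 0.0147). Klf10 was 13.0 and 14.3 CPM in Th17n at 25 and 1 mM and fell from 6.75 to 1.197 CPM in Th17p (-2.59 ± 0.26, adjusted p = 0.0169). Cxcr3 was 7.34 and 9.26 CPM in Th17n and fell from 17.8 to 6.85 CPM in Th17p (-1.71 ± 0.16, adjusted p = 0.0147). The progranulin gene Grn (-1.32 ± 0.14), Icam1 (-0.99 ± 0.12), the protease gene Adam10 (-0.94 ± 0.12), Epb41l2 (-1.17 ± 0.16) and Kidins220 (-1.08 ± 0.15) also had lower responses in Th17p, and the autophagy gene Gabarapl1 a higher one (1.11 ± 0.14). The other 2, named after their values were seen, were Frmd6 (-1.39) and Rab20 (1.2). The count was 0 without Th17n 1 mM mouse 1, Th17n 25 mM mouse 1, Th17n 25 mM mouse 2, Th17p 25 mM mouse 1 or Th17p 25 mM mouse 2, 1 without Th17n 1 mM mouse 2, and 5 without either Th17p 1 mM library. It was 187 with the mouse as a block, 112 with the DESeq2 Wald test and 452 without the filter on low counts, and 1635 genes had an unadjusted p below 0.05. Of the panel, Il17a (-1.11 ± 0.39, adjusted p = 0.298) did not pass, nor did Il17f (-1.38 ± 0.40, 0.239), Csf2 (1.93 ± 0.41, 0.149) and Txnip (-1.64 ± 0.30, 0.114). With the block the last 3 passed, at adjusted p of 0.0123, 0.00162 and 0.00552. All 4 passed without the filter on low counts, at adjusted p of at most 2.95e-08, and Csf2 (6.89e-05) and Txnip (5.71e-05) passed in DESeq2.

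By lists, 20 of 34 differed in response by camera, none of which did so with an estimated correlation. Interferon response genes had lower responses in Th17p (median difference -0.94, adjusted p = 5.05e-20, adjusted p = 0.0792 with an estimated correlation; 0 genes over all genes and 16 adjusted over the list alone). So did MondoA and ChREBP targets (-2.11, adjusted p = 4.43e-11, adjusted p = 0.101 with an estimated correlation; Klf10 over all genes and 3 adjusted over the list alone) and TGF-beta response genes (-0.36, adjusted p = 4.39e-05, adjusted p = 0.101 with an estimated correlation; 3 adjusted over the list alone). Oxidative phosphorylation (0.30, adjusted p = 1.8e-11), TCA cycle (0.29, adjusted p = 2.6e-06) and MYC targets (0.33, adjusted p = 2.6e-06) had higher responses in Th17p, with adjusted p = 0.363, 0.414 and 0.52 with an estimated correlation and 0 genes adjusted over the list alone. These 6 lists kept their calls without each library in turn. Hypoxia and HIF targets (-0.12, adjusted p = 0.261), glycolysis (0.13, adjusted p = 0.277) and the pathogenic signature (-0.40, adjusted p = 0.344) were not called, although hypoxia targets were without Th17n 25 mM mouse 1 (1.07e-05), glycolysis genes without Th17n 25 mM mouse 2 (0.00402) and the signature without Th17n 1 mM mouse 2 (0.0112).

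At 25 mM glucose, Gzmb, Il22 and Csf2 were among the genes higher in Th17p than in Th17n cells, and Aqp3, Ctsw, Maf and Foxp3 among those lower. Gzmb was higher by 6.82 ± 0.42 on the log2 scale (edgeR adjusted p = 1.16e-05), Il22 by 5.34 ± 0.55 (from 6.62 ± 6.2 to 270 ± 26 CPM; SD, n = 2 per group) and the proteoglycan gene Lum by 8.17 ± 0.28. Serpinb6b was higher by 4.87 ± 0.28, Pdzk1ip1 by 4.01 ± 0.17, the CD30 ligand gene Tnfsf8 by 3.91 ± 0.27 and Ccl5 by 3.73 ± 0.57. Il23r was higher by 3.69 ± 0.28 and Csf2 by 2.35 ± 0.28. The aquaporin gene Aqp3 was lower (-9.69 ± 0.29, adjusted p = 3.79e-07, from 388 to 0.481 CPM). So were Tmem176b (-7.56 ± 0.23), Pdpn (-7.54 ± 0.35), Tmem176a (-7.11 ± 0.19), Ctsw (-7.01 ± 0.22) and Maf (-6.61 ± 0.17, from 58.6 to 0.592 CPM). Cyp11a1 (-6.30 ± 0.32), Foxp3 (-6.07 ± 0.36) and Il10 (-3.52 ± 0.28) were lower as well. Olfm2 had 5099 UMIs in Th17n and 2 in Th17p, a ratio of 2426 (95% counting interval 671 to 20038). Il17a was lower in Th17p (-1.61 ± 0.28, adjusted p = 0.00341), and Il17f was too (-1.24 ± 0.28, adjusted p = 0.0132), the latter not without Th17n 25 mM mouse 2 (0.0941), Th17p 25 mM mouse 1 (0.0796) or Th17p 25 mM mouse 2 (0.0516). Tbx21 was higher (2.15 ± 0.62, adjusted p = 0.0338), a call lost without Th17n 25 mM mouse 1 (0.159), without Th17p 25 mM mouse 2 (0.167) and in DESeq2 (0.0732). In all 3212 genes differed, 1406 higher and 1806 lower. This was 1638 without Th17n 25 mM mouse 2, 1885 without Th17p 25 mM mouse 1 and 1758 without Th17p 25 mM mouse 2.

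The signatures of both states separated the groups at 25 mM. The pathogenic signature was higher in 15 of 16 genes (15 adjusted over the list alone), with Il3 at 8.26 ± 0.53 and Icos at 2.30. Its median was 2.22, at a camera adjusted p = 5.82e-19 and an adjusted p = 0.0252 with an estimated correlation. The non-pathogenic signature was lower in 6 of 7 (6 adjusted over the list alone), with Il9 at -6.05 ± 0.40 and the aryl hydrocarbon receptor gene Ahr at -3.75. Over the whole list the median change was -3.52 (adjusted p = 4.98e-28, and adjusted p = 0.0105 with an estimated correlation). In the Th17 program 15 of 23 were lower and 6 higher (the same adjusted over the list alone), with the chemokine receptor gene Ccr6 at -2.13 ± 0.09. This gave a median of -1.03 and a camera adjusted p = 2.24e-13 (adjusted p = 0.114 with an estimated correlation). Interferon response genes were higher in 17 of 34 and lower in 3 (18 and 3 adjusted over the list alone), with Gbp5 at 2.27 ± 0.24, and 9 higher without Th17n 25 mM mouse 2 and 11 without Th17p 25 mM mouse 1. The list had a median of 1.28 (camera adjusted p = 0.000143; adjusted p = 0.179 with an estimated correlation). The Th1 list was higher in 11 of 18 and lower in 3 (the same adjusted over the list alone), with Il12rb2 at 2.93 and the NK receptor gene Klrd1 lower (-3.92 ± 0.40). As a set its median was 1.54, with adjusted p = 2.93e-05, and adjusted p = 0.178 with an estimated correlation. p53 targets were higher in 12 of 16 (14 adjusted over the list alone), with Phlda3 at 1.70 ± 0.14. Camera gave adjusted p = 1.46e-10 at a median of 0.70, and adjusted p = 0.0615 with an estimated correlation. The ER unfolded protein response was higher in 14 of 21 (16 adjusted over the list alone), where 5, 2, 2 and 6 were higher without Th17n 25 mM mouse 1, Th17n 25 mM mouse 2, Th17p 25 mM mouse 1 and Th17p 25 mM mouse 2. Across its members the median was 0.49 (camera adjusted p = 0.000143, and adjusted p = 0.741 with an estimated correlation). Treg genes were lower in 7 of 17 and higher in 2 (8 and 2 adjusted over the list alone), with the ectonucleotidase gene Nt5e at -4.58. Its median was -0.64, at a camera adjusted p = 2.06e-06 and an adjusted p = 0.138 with an estimated correlation. Cholesterol synthesis was lower in 14 of 24 (1 up and 15 down adjusted over the list alone), with 8 lower without Th17n 25 mM mouse 2 and 7 without Th17p 25 mM mouse 1. Over the whole list the median change was -0.44 (adjusted p = 0.000167, and adjusted p = 0.741 with an estimated correlation). TGF-beta response genes were lower in 8 of 16 and higher in 2 (8 and 3 adjusted over the list alone; median -0.48, adjusted p = 0.00358), with adjusted p = 0.141 with an estimated correlation. Smaller calls, with adjusted p from 0.741 to 0.909 with an estimated correlation, were those of mitochondrially encoded genes (6 higher of 13, adjusted p = 0.00358), exhaustion (5 higher and 2 lower of 13, among them Tigit at 3.46 ± 0.22, adjusted p = 0.0215), ATF4 targets (10 higher and 1 lower of 28, adjusted p = 0.0193) and G2/M genes (7 lower of 37, adjusted p = 0.0215). Adjusted over the list alone these had 11 higher, 5 higher and 4 lower, 12 higher and 3 lower, and 4 lower. The mitochondrial list lost its call in deep cells (0.0544), ATF4 targets without Th17n 25 mM mouse 1 (0.0538) or Th17p 25 mM mouse 1 (0.118), and G2/M genes without Th17n 25 mM mouse 2 (0.0934) or Th17p 25 mM mouse 1 (0.056). With 1 library left out, the counts fell to 5 lower for TGF-beta genes (Th17p 25 mM mouse 2), 6 higher for ATF4 targets (Th17p 25 mM mouse 1), and 2, 3 and 1 higher for mitochondrial genes (Th17n mouse 2, Th17p mouse 1 and Th17p mouse 2). For G2/M genes they fell to 4, 0, 0 and 1 lower (Th17n mouse 1 and 2, Th17p mouse 1 and 2). MondoA and ChREBP targets (3 higher and 1 lower of 4, the same adjusted over the list alone; median 1.31, adjusted p = 0.232) were called with the block (0.0172) and without Th17p 25 mM mouse 2 (0.0458). Ribosomal proteins did not pass as a list (0 of 78 called, over all genes or adjusted over the list alone; adjusted p = 0.321), though they did in deep cells (0.0285). Hypoxia and HIF targets (median 0.27) and autophagy genes (-0.24) were not called in the reported fit either. Both were called in deep cells (0.29 and -0.28, camera adjusted p = 0.0416 each). Each was also called in fits with a library left out. The hypoxia median was then 0.50 without Th17n 25 mM mouse 1 and 0.30 without Th17p 25 mM mouse 2. The autophagy median was -0.28 without Th17p 25 mM mouse 1. The barcodes left out for over 10% mitochondrial UMIs made up 17.4 ± 0.316% in Th17p and 5.25 ± 1.03% in Th17n at 25 mM, and 16.5 ± 0.05% and 10.9 ± 0.173% at 1 mM.

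At 1 mM glucose, Gzmb, Il22 and Csf2 were again higher in Th17p than in Th17n, and Aqp3, Ctsw, Maf and Foxp3 again lower. Among the higher genes were Gzmb (6.2 ± 0.33, edgeR adjusted p = 5.3e-06), Serpinb6b (5.55 ± 0.29), Il22 (5.24 ± 0.57), Tigit (4.66 ± 0.26), Csf2 (4.28 ± 0.31, from 3.62 to 71.5 CPM), Il12rb2 (3.85 ± 0.40) and Il23r (2.89 ± 0.35). Aqp3 (-10.67 ± 0.33), Tmem176a (-8.61 ± 0.23), Tmem176b (-8.16 ± 0.25), Pdpn (-7.66 ± 0.41), Ctsw (-7.02 ± 0.23), Maf (-6.87 ± 0.18, adjusted p = 2.47e-07), Il9 (-5.67 ± 0.40, from 1145 to 22.3 CPM), Il10 (-5.44 ± 0.35) and Foxp3 (-5.17 ± 0.47) were lower. Il17a (-2.72 ± 0.29, adjusted p = 0.000197) and Il17f (-2.61 ± 0.30) were lower too, while Tbx21 (1.10 ± 0.66, adjusted p = 0.246) and Txnip (-0.46 ± 0.24, adjusted p = 0.181) did not pass, except with the mouse as a block (0.00745 and 0.0305) and without the filter on low counts (2.89e-09 and 0.00898). Olfm2 had 10663 UMIs in Th17n and 2 in Th17p, a ratio of 3655 (95% counting interval 1012 to 30182). In all 3485 genes differed, 1521 higher and 1964 lower. This was 1957 without Th17n 1 mM mouse 1 and 2100 without Th17n 1 mM mouse 2.

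The pathogenic signature was higher in 12 of 16 genes at 1 mM (12 adjusted over the list alone). This gave a median of 1.88 and a camera adjusted p = 1.51e-15 (adjusted p = 0.0323 with an estimated correlation). The non-pathogenic signature was lower in 7 of 7 (7 adjusted over the list alone). The list had a median of -3.86 (camera adjusted p = 5.86e-29; adjusted p = 0.00988 with an estimated correlation). TGF-beta response genes were lower in 10 of 16 and higher in 1 (11 and 1 adjusted over the list alone), with the receptor gene Tgfbr1 at -2.69 ± 0.16. As a set its median was -0.84, with adjusted p = 3.85e-07, and adjusted p = 0.045 with an estimated correlation. The Th17 program was lower in 14 of 23 and higher in 7 (16 and 7 adjusted over the list alone). Camera gave adjusted p = 1.38e-16 at a median of -1.33, and adjusted p = 0.045 with an estimated correlation. p53 targets were higher in 9 of 16 and lower in 1 (11 and 1 adjusted over the list alone). Across its members the median was 0.45 (camera adjusted p = 0.000184, and adjusted p = 0.23 with an estimated correlation). Treg genes were lower in 7 of 17 and higher in 2 (7 and 3 adjusted over the list alone; median -0.73, adjusted p = 0.00104, and adjusted p = 0.355 with an estimated correlation). The ribosomal list (16 higher of 78, adjusted p = 0.000159), oxidative phosphorylation (11 higher of 42, adjusted p = 0.00199) and MYC targets (6 higher of 24, adjusted p = 0.0108) were higher in Th17p. G2/M genes (14 lower of 37, adjusted p = 0.00104) and S phase genes (8 lower of 30, adjusted p = 0.0453) were lower. Adjusted over the list alone these were 6, 11 and 5 higher and 22 and 8 lower, and all had adjusted p = 0.878 with an estimated correlation. MYC targets lost their call without Th17p 1 mM mouse 2 (0.179), G2/M genes without Th17p 1 mM mouse 1 (0.169), and S phase genes without Th17n 1 mM mouse 2 (0.141), without Th17p 1 mM mouse 1 (0.629) and with DESeq2 size factors (0.0541). The Th1 list was higher in 6 of 18 and lower in 5 (7 and 5 adjusted over the list alone; adjusted p = 0.0334, and adjusted p = 0.681 with an estimated correlation), a call lost without Th17p 1 mM mouse 2 (0.0572) and with the block (0.066). Without Th17n 1 mM mouse 1 or 2, 3 ribosomal genes were higher, and 1 without Th17p 1 mM mouse 1. Oxidative phosphorylation kept 3, 7 and 3 without Th17n mouse 1, Th17n mouse 2 and Th17p mouse 2, and MYC targets 0, 3 and 2. G2/M genes had 2, 4 and 33 lower without Th17n mouse 2, Th17p mouse 1 and Th17p mouse 2, and S phase genes 2, 1, 2 and 21 without Th17n mouse 1 and 2 and Th17p mouse 1 and 2. The exhaustion list (7 higher and 3 lower of 13, the same adjusted over the list alone; adjusted p = 0.0686) was called with the block (0.0429), in deep cells (0.032), without Th17n 1 mM mouse 2 (0.0371) and without Th17p 1 mM mouse 1 (0.0048). It had 3 higher without Th17n 1 mM mouse 1 or Th17p 1 mM mouse 2. Interferon response genes were not called at this glucose level (4 higher, 10 lower of 34, 5 and 11 adjusted over the list alone; median -0.44, adjusted p = 0.159), except without Th17p 1 mM mouse 2 (0.0427) and with the block (0.0191). Across the 25 mM and 1 mM comparisons, which share no library, 778 genes were higher in both (170 for independent lists), 1234 lower in both (282) and 13 opposite (438), with r = 0.83 across genes. The number of the same direction, 2012, was 1329 without Th17n 25 mM mouse 2 and 599 in shallow cells.

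Shares of cells with a UMI of a gene were taken after thinning each cell to 5000 UMIs and are given for 4 panel genes. Il17a was seen in 31.2 ± 4.2% of Th17n cells at 25 mM and 17.8 ± 4.99% at 1 mM, and in 13.5 ± 0.52% and 4.23 ± 0.298% of Th17p cells (SD, n = 2 mice). Without thinning the shares were 38.6, 20.7, 15.8 and 5.43%. Il17f was seen in 74.1, 45.6, 27.7 and 8.8% of cells in the same order, and without thinning in 82.3, 56.0, 33.8 and 13.2%. In Th17p cells Csf2 was seen in 7.07 ± 0.917% at 25 mM and 14.8 ± 1.92% at 1 mM (12.7 and 27.1% without thinning), and Gzmb in 6.54 ± 1.06% and 21.3 ± 0.83% (13.2 and 33.2% without thinning). Free RNA alone would give Il17a UMIs in 6.77 and 6.89% of Th17n cells at 25 mM and 0.879 and 1.51% at 1 mM, and in 3.75 and 3.22% of Th17p cells at 25 mM and 0.191 and 0.149% at 1 mM, and it would give Csf2 or Gzmb UMIs in at most 0.485% of cells of any library. For Il17f it would give 8.09 and 8.44% in Th17n at 25 mM, 1.38 and 1.45% in Th17n at 1 mM, 6.005 and 8.14% in Th17p at 25 mM, and 0.204 and 0.579% in Th17p at 1 mM. Among positive cells, Il17a UMIs per cell fell from 28.2 ± 0.197 to 11.0 ± 0.689 in Th17p and from 29.0 to 19.4 in Th17n. Csf2 UMIs per positive Th17p cell fell too, from 3.50 ± 0.233 to 2.04 ± 0.062, while the share of positive cells rose. For Gzmb in Th17p they were 2.73 ± 0.404 at 25 mM and 2.68 ± 0.059 at 1 mM. Thinning left out 457 and 310 cells in Th17n at 25 mM, 293 and 221 in Th17n at 1 mM, 392 and 299 in Th17p at 25 mM and 103 and 130 in Th17p at 1 mM. These shares were not tested. The free RNA values are for cells before thinning, so they belong beside the shares without thinning.

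**Figure D4:**
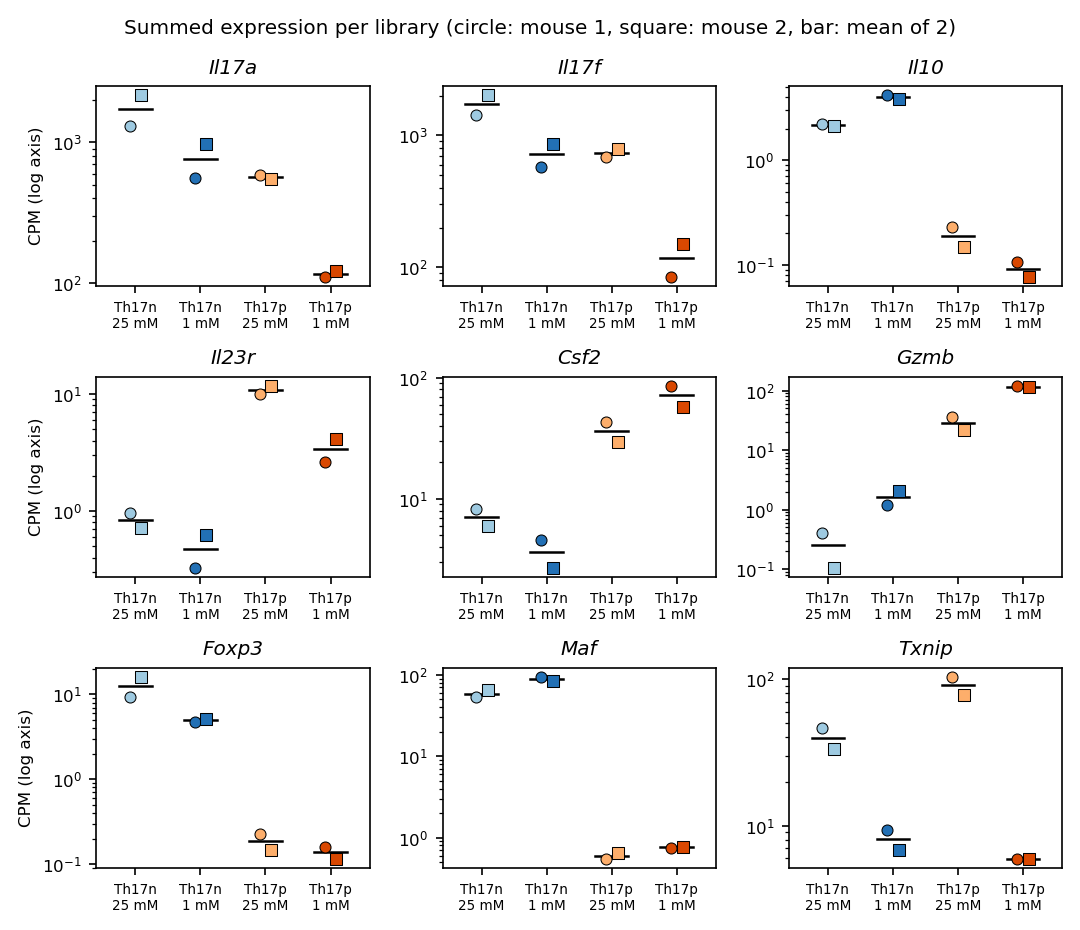
CPM (log axis) of 9 panel genes in each library, by group, with circles for mouse 1, squares for mouse 2 and a bar at the mean. Il17a means run from 1726 CPM in Th17n at 25 mM to 116 CPM in Th17p at 1 mM, and Maf means from 88.7 CPM in Th17n at 1 mM to 0.592 CPM in Th17p at 25 mM.

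In the mm10 annotation, the Il17a gene (ENSMUSG00000025929) spans chromosome 1 from 20730905 to 20734496 on the plus strand and Il17f (ENSMUSG00000041872) lies next to it from 20777146 to 20790617 on the minus strand. Txnip (ENSMUSG00000038393) spans chromosome 3 from 96557957 to 96561883. Csf2 (ENSMUSG00000018916) spans chromosome 11 from 54247271 to 54249667, Gzmb (ENSMUSG00000015437) chromosome 14 from 56258838 to 56262260, Klf10 (ENSMUSG00000037465) chromosome 15 from 38291463 to 38300706 and Jun (ENSMUSG00000052684) chromosome 4 from 95049034 to 95052222. All values are sums over whole genes, so no part of a gene is singled out.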

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

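The deep-cell tests and both tests without 10% of cells were chosen after the results they bear on had been seen. So was the test of interferon-high cells in Th17p alone. The test without 5% of cells on the difference of responses was set beforehand. It was set for cells with the most UMIs of the list, but cells with the largest share of such UMIs were removed. The SE of a list median was taken over resampled genes of the list and covers no variation between mice.

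The glucose response of 9 named genes differed between Th17p and Th17n by a test of the difference itself (log2 change in Th17p minus that in Th17n, edgeR adjusted p below 0.05). The differences were -1.46 for Jun, -1.71 for Cxcr3, -2.59 for Klf10, -1.32 for Grn, -0.99 for Icam1, -0.94 for Adam10, -1.17 for Epb41l2, -1.08 for Kidins220 and 1.11 for Gabarapl1. Leaving out a library ended these calls in most cases. For Icam1, Adam10, Epb41l2 and Kidins220 the call was lost whichever library was left out. The few genes called with a library left out were in part not among those of the reported fit.

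By camera at its preset correlation, 20 gene lists also differed in response, and with an estimated correlation 0 did. Lists with a lower response in Th17p were MondoA and ChREBP targets (median difference -2.11), the interferon response (-0.94), Th1 (-0.46), TGF-beta response (-0.36), the ER unfolded protein response (-0.32), mitochondrially encoded genes (-0.27), the Th17 program (-0.26), the non-pathogenic signature (-0.26), p53 targets (-0.22), ATF4 targets (-0.17) and G2/M genes (-0.15). Lists with a higher one were MYC targets (0.33), the pentose phosphate pathway (0.30), oxidative phosphorylation (0.30), the TCA cycle (0.29), serine and one-carbon metabolism (0.23), cholesterol synthesis (0.23), NRF2 targets (0.23), cytosolic ribosomal proteins (0.22), and glutamine and amino acid use (0.16). Calls were lost without 1 library for ATF4 targets (adjusted p = 0.081 without Th17p 25 mM mouse 1 and 0.221 without Th17p 1 mM mouse 2), the ER list (0.109) and cholesterol synthesis (0.199), both without Th17p 1 mM mouse 2, the pentose phosphate and the serine list (0.0514 each, without Th17p 1 mM mouse 2), mitochondrially encoded genes (0.0682 without Th17p 25 mM mouse 2), ribosomal proteins (0.113 without Th17n 1 mM mouse 2 and 0.0594 without Th17p 1 mM mouse 1), the Th17 program (0.316 without Th17p 1 mM mouse 1) and Th1 (0.118 without Th17p 1 mM mouse 1 and 0.0738 without Th17n 25 mM mouse 2). The non-pathogenic list lost its call without Th17n 25 mM mouse 1 (0.125), Th17n 1 mM mouse 2 (0.106), Th17p 1 mM mouse 1 (0.455) and Th17p 25 mM mouse 2 (0.0934), and the glutamine list without each library but Th17n 25 mM mouse 1 and Th17n 1 mM mouse 2 (from 0.0560 to 0.107). G2/M genes lost theirs without Th17n 25 mM mouse 1 (0.332), Th17n 1 mM mouse 2 (0.837), Th17p 25 mM mouse 2 (0.182) and Th17p 1 mM mouse 1 (0.0588), the last with a median of 0.078. In deep cells calls were lost for mitochondrially encoded genes (median -0.11, adjusted p = 0.318), Th1 (-0.13, 0.0539) and the non-pathogenic list (-0.22, 0.247). With DESeq2 size factors they were lost for the glutamine list (0.052), G2/M genes (0.0575) and the non-pathogenic list (0.0511).

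The median gene of the interferon response list fell at 1 mM glucose in Th17p (-0.93) and was at 0.16 in Th17n, without a call. The summed UMIs of the list per thinned cell were lower at 1 mM in both, with medians of 9 and 9 at 25 mM against 6 and 7 at 1 mM in Th17n, and of 9 and 9 against 4 and 6 in Th17p. A first candidate explanation is a small set of interferon-high cells in Th17p at 25 mM, where 8.76 and 9.32% of cells held at least 20 UMIs of the list, against 0.503 and 1.08% of Th17p cells at 1 mM. In Th17n these were 3.86 and 3.76% at 25 mM and 1.79 and 3.98% at 1 mM. The clustering also gave a cluster of 192 cells led by Ccl5, Isg15 and Ifit1. It held 61 and 31 cells of the Th17p libraries at 25 mM and 14 and 10 at 1 mM. Of the Th17n libraries it held 12 and 6 cells at 25 mM and 37 and 21 at 1 mM. Its contribution was not tested. The 5% of cells with the largest share of UMIs of the list were left out of each library. The median fall within Th17p was then -0.89 (SE 0.186), but 5.11 and 5.29% of the Th17p cells kept at 25 mM still held at least 20. Without 10% of cells, which left 2.19 and 2.64%, it was -0.83 (SE 0.176), which argues against the cells removed as its whole source and leaves open what the remaining ones add. The median difference between the responses, -0.88 (SE 0.21) without 5% and -0.875 (SE 0.239) without 10%, lay too near the bound set for it to decide. Among deep cells the difference was -0.95 (SE 0.347), which likewise leaves a contribution of shallow cells open. A difference in interferon signalling between the culture conditions remains an untested hypothesis, and the call rests on the preset correlation.

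UMIs outside called cells, data that the comparisons do not use, made up 23.7% of all UMIs in Th17n 1 mM mouse 1, 30.1% in Th17n 25 mM mouse 1, 24.9% in Th17n 1 mM mouse 2 and 22.2% in Th17n 25 mM mouse 2. In Th17p they were 28.01% in 1 mM mouse 1 and 29.4% in 1 mM mouse 2, but 45.2% in 25 mM mouse 1 and 43.6% in 25 mM mouse 2.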

How the results depend on the processing

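Leave-out fits of the gene lists and the deep-cell and shallow-cell fits were chosen after the data had been seen, and all other alternatives beforehand. Counts of genes kept within 1.5 times of the reported value with DESeq2 size factors, without the filter on low counts, with the mouse as a block, with the DESeq2 Wald test, with all barcodes, with at least 1000 genes per cell, with doublets kept, with equal cells and depth, with only the 4 libraries and with deep cells, apart from the difference of responses. With 1 library left out, the counts ran from 1472 to 2839 for glucose in Th17n (reported 4289), from 2171 to 3753 for glucose in Th17p (4025), from 1638 to 2255 for Th17p against Th17n at 25 mM (3212), from 1957 to 3095 at 1 mM (3485), and from 0 to 5 for the difference of responses (11). At counts of 0 in edgeR, 962 to 1764 genes had an unadjusted p below 0.05. Fits without a library have fewer residual degrees of freedom, which lowers the power of each. Among shallow cells, with fewer UMIs and 10024 genes tested, the counts were 2117 for glucose in Th17n, 1307 at 25 mM and 1401 at 1 mM. The count of 11 for the difference of responses was 452 without the filter, 187 with the mouse as a block, 112 with the DESeq2 Wald test, 3 in deep cells and 32 in shallow cells, and the cause was not tested. The number of genes moving alike with glucose in Th17n and Th17p (2494) ran from 1165 to 2473 with a library left out and was 1339 in shallow cells.

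With an estimated correlation, camera called 0 lists for glucose in Th17n (16 with the preset), 0 in Th17p (11), 2 at 25 mM (14), 4 at 1 mM (12) and 0 for the difference (20). Leave-out fits called from 15 to 17, 11 to 16, 13 to 17, 12 to 14 and 15 to 21. Over lists and contrasts, 5 calls were lost with DESeq2 size factors, 2 were lost and 5 gained with the block, and 5 were lost and 11 gained in deep cells. Apart from the genes and lists named in the report, the block changed no other call among the values printed here. Without Th17p 1 mM mouse 1, the median difference of responses turned to 0.17 for S phase genes (adjusted p = 0.0262) and to 0.078 for G2/M genes (0.0588), against lowest values of -0.35 and -0.45 without Th17p 1 mM mouse 2. The direction of both therefore rests on single libraries.

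Values of named genes that turned sign included those of Scd2 in deep cells for glucose in Th17p (0.083), and, in shallow cells, Eci1 (0.07), mt-Atp6 (-0.15) and mt-Cytb (-0.065) for glucose in Th17p and Dscc1 at 25 mM (0.079), none of them called there, and the cause was not tested. Over all combinations of named gene, contrast and alternative, unreported genes among them, 10698 were counted as unchanged. Of the rest, 712 lost a call, 211 gained one, and 6 turned sign with a call in either fit. A sign that turned without a call in either fit was counted as unchanged, so the number of all turned signs is not given. Shallow cells alone lost 35 and 23 calls of named genes for glucose in Th17n and Th17p, and 37 and 24 at 25 and 1 mM. A fit without cells of other types gave no value, since no such cluster was found.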

Other observations

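Tests on deep cells and on the lower part of cells by G2/M share were chosen after the results had been seen; those on cells with few G2/M UMIs, on ribosomal and mitochondrial genes, on free RNA and on the correlation between mice were set beforehand.

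Il2, which encodes a growth factor of T cells and was chosen after its values were seen, was seen after thinning in 35.9% of Th17p cells at 25 mM and 42.0% at 1 mM, and in 19.4 and 21.5% of Th17n cells. Free RNA alone would give an Il2 UMI in 10.9 and 17.8% of Th17p cells at 25 mM and 3.85 and 6.87% at 1 mM, and in 4.67 and 3.36% of Th17n cells at 25 mM and 2.64 and 2.335% at 1 mM, so part of these shares is background. Mean UMIs per positive cell were 30.2 and 19.4 in Th17p and 23.2 and 16.4 in Th17n. The free RNA values are for cells before thinning, and thinned cells would hold less, so they cannot be set directly beside these shares. The shares were not tested or corrected for free RNA.

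Hypoxia and HIF targets rose at 1 mM glucose in both conditions, though not as a list with an estimated correlation (camera adjusted p = 0.46 and 0.435). A hypothesis is that low glucose itself drives these targets. In deep cells the medians were 1.36 in Th17n (SE 0.184) and 1.09 in Th17p (SE 0.163), against 1.38 and 1.15 in all cells. This argues against shallow cells as the whole source. In the cells with a low share of G2/M UMIs the medians were 1.33 (SE 0.202) and 1.28 (SE 0.118), so the rise was present there too. These cells made up 72.2 and 65.2% of Th17n libraries at 1 mM and 31.5 and 23.5% at 25 mM. In Th17p they made up 86.9 and 75.7% against 39.1 and 30.3%. Division may therefore still differ with glucose inside this subset, and S phase was not matched, so a contribution of dividing cells stays open. Cells with at most 2 G2/M UMIs gave 1.16 and 1.03 but decide nothing, since such a limit picks cells of low depth (medians of 2457 to 5572 UMIs per library). Without ribosomal and mitochondrial genes in the library sizes the medians were 1.36 and 1.14. Each SE of a list median was taken over resampled genes of the list and covers no variation between mice. Oxygen supply, cell density and medium acidity, which may differ with glucose, were not measured and remain open.

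By camera at its preset correlation, though not with an estimated one (adjusted p = 0.678 and 0.501), cytosolic ribosomal protein transcripts also rose in both conditions. In deep cells their medians were 0.37 in Th17n and 0.50 in Th17p, against 0.40 and 0.64 in all cells, which argues against shallow cells as the whole source. In cells with a low share of G2/M UMIs they were 0.36 and 0.57, so the rise was present there too, but division may still differ inside that subset. After subtraction of free RNA they were 0.40 and 0.64. Cells with at most 2 G2/M UMIs, at 0.72 and 1.11, decide nothing here either. The log2 changes also carry the TMM factors, which were lower at 1 mM than at 25 mM. These were 0.934 and 0.982 against 1.08 and 1.04 in Th17n, and 0.858 and 0.91 against 1.11 and 1.12 in Th17p. The changes are therefore larger than those of the unscaled ribosomal share of UMIs, more so in Th17p. A lower total of other transcripts per cell could raise this share with no change in ribosomal transcripts per cell and stays open, because UMI counts give shares, not absolute amounts.

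A hypothesis that low glucose moves Th17p cells toward the Th17n profile was tested across mice, so that no library was shared. The glucose response of Th17p in mouse 1 and the Th17p minus Th17n difference at 25 mM in mouse 2 correlated at r = -0.024 across genes, and the opposite pairing at r = -0.023, where the hypothesis needed values below -0.1. An r over all genes cannot exclude that single lists or genes moved toward the Th17n profile while others moved away from it. Across the same pairs of mice, the glucose responses of Th17n and Th17p correlated at r = 0.57 and 0.619.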
